A study of Mus musculus with 4 samples.

How the data were processed

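Total RNA from leukemic whole bone marrow was hybridised to Affymetrix mouse gene arrays, 1 array per sample. The deposited values are probe set intensities summarised by RMA in Affymetrix Expression Console, per the submitters' processing notes, with software versions not given in the sources used here. The deposited intensities are on a linear scale: array medians over all probe sets ran from 65.0 to 67.3. A log2 scale had been assumed when the design was set, so log2 was taken here before any test and no value was added to the intensities. After that step gene levels ran from 1.41 to 13.8. The table of 4 arrays was used whole, with 0 columns of sample values left out. No background correction or normalization was repeated for the main results, so they carry the scaling between arrays that the deposited values have, and a difference in total RNA between samples would not show in them.

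The table holds 35556 probe sets. The platform annotation pairs 21789 of them with 1 gene symbol and 1621 with several, and does not list the other 12146. Entrez gene identifiers matched 21698 of the single-symbol probe sets to RefSeq genes of assembly GRCm38.p6, and 0 symbols changed. The build behind the array annotation is not given in the sources used here, so no coordinates are printed and the RefSeq table served for names, chromosome membership and the order of neighbouring genes. Only probe sets with 1 symbol were named. For the 999 genes with more than 1 probe set, the probe set with the highest mean over the 4 arrays stood for the gene, which left 19938 genes, with no filter on dim probe sets.

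Genotypes were taken from the sample labels, 2 arrays each. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided) with genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. The fit had 2 residual and 3.41 prior degrees of freedom, and the median moderated SE of a gene's difference was 0.17 on the log2 scale. The labels do not say that the samples came from separate animals. A gene's p-value measures the spread between these samples, which may therefore be partly technical. Gene lists for cell types, pathways and sample quality were fixed before the data were examined, 34 in all, of which 33 were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists, at least 5 measured members), and the sex-linked list was only read per array. Camera with an estimated correlation and fry served as alternatives. By the preset correlation, the main camera p-values take list members as nearly independent, also where an array is left out. Adjusted p-values over a list alone use the same per-gene p-values.

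The deposited values carry no detection calls. For 5 called genes at least 1 array of the lower genotype did not exceed 4.09, the highest level of a Y-linked gene. Their fold is a lower bound, taken from the mean of the brighter genotype against the mean of the dimmer one with each array at 4.09 or its own level, whichever was higher. This limit was chosen after seeing the data, and background can differ between probe sets. The bound does not allow for the spread between arrays. The genes named were set by a rule fixed before the data were examined. It takes Hes1 and Flt3, and every list member with an adjusted p under 0.05. It adds the 12 largest positive and 12 largest negative differences among genes with an adjusted p under 0.05 and non-overlapping genotypes, leaving aside unnamed transcripts, olfactory and vomeronasal receptors and small RNAs. For each list described, it takes up to 4 members with the smallest unadjusted p. Xist, the Y-linked genes and, in the closing observations, a neighbour of Hes1 are named outside this rule as checks, the neighbour after its value was seen.

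The test was tried on simulated data, 20 simulations of 19938 genes with the real genes' means. Each gene's spread was drawn at random from the prior that limma fitted to these data. It called 14.8% of genes changed 2-fold, 88.1% of those changed 4-fold, 96.0% of those changed 8-fold and 98.6% of those changed 16-fold, and 5.2% of its calls were false. A simulated list of 20 genes shifted by 0.5 (log2) was called in 20 of 20 simulations, and on average 0.05 of 32 unshifted lists was called. The simulated genes were independent, which real list members are not. Their spread followed the test's own model and was equal in both genotypes, so the share of false calls does not check that model. On the real arrays 109 genes lay at least 2-fold apart within wild type and 683 within Hes1-null.

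The alternatives fixed in advance included the replicate number as a block, a further quantile normalization, centring each array on its median, and filters at the 25th percentile and the median of gene level. Others were moderation without the intensity trend or with robust estimation, array weights, the mean of a gene's probe sets, and every probe set tested on its own. Other thresholds, an ordinary two-sample test without moderation, other tests of lists and leaving out each array in turn completed them. Testing each probe set with 1 gene symbol on its own was added after seeing the data. With an array left out, the lone array of its genotype was assumed to vary like the others.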

Results

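Whole bone marrow was profiled from C57BL/6 mice with leukemia driven by MLL-AF9, a fusion oncogene of acute myeloid leukemia. The series holds 4 microarrays, 2 from leukemic marrow labelled Hes1-null and 2 from leukemic marrow labelled wild type. Hes1 encodes a transcriptional repressor that Notch signalling induces. The comparison addresses whether Hes1 carries the restraint that Notch signalling places on this leukemia. Levels are given on the log2 scale, and a difference is Hes1-null minus wild type with its standard error (SE, n = 2 arrays per genotype). The median over all probe sets (linear scale) was 67.3 and 65.0 on wild-type replicates 1 and 2. It was 65.1 and 66.6 on Hes1-null replicates 1 and 2. The small number of arrays limits the precision of every value. Across genes the wild-type arrays correlated at r = 0.995 and the Hes1-null arrays at r = 0.982. Within the respective genotype, 109 and 683 genes lay at least 2-fold apart.

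The targeted gene did not separate the genotypes. Hes1 lay at 5.59 and 5.79 on the wild-type arrays and at 5.43 and 5.84 on the Hes1-null arrays, a difference of -0.06 ± 0.18 (adjusted p = 0.968). Its single probe set was dim in both genotypes, at the 38.0th percentile of gene levels, and the labels do not say whether it lies in the deleted part. The level of Hes1 therefore does not check the genotype labels, and Hes1-null means labelled Hes1-null throughout. Xist, the RNA that coats the inactive X chromosome of female cells, lay at 11.7 or above on both wild-type arrays and on Hes1-null replicate 1. On Hes1-null replicate 2 it lay at 7.25. The 4 measured Y-linked genes Kdm5d, Eif2s3y, Uty and Usp9y did not exceed 4.09 on any array.

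Smpdl3a, which encodes a phosphodiesterase related to acid sphingomyelinase, rose 22.7-fold in Hes1-null marrow (log2 difference 4.50 ± 0.22, adjusted p = 0.0141). Sh2d1b1, encoding the adaptor EAT-2 of SLAM family receptors, rose by a measured 4.40 ± 0.21 (adjusted p = 0.0141), at least 19.6-fold with background allowed for. Ikzf2, encoding the Ikaros family transcription factor Helios, rose 12.7-fold (3.67 ± 0.16), and the AP-1 subunit gene Jun rose 6.49-fold (2.70 ± 0.16, adjusted p = 0.0231). In the other direction, Lipo3, a member of the acid lipase family, differed by a measured -3.62 ± 0.18 (adjusted p = 0.0141). With background allowed for it was at least 11.6-fold lower in Hes1-null marrow. Vcam1, an adhesion molecule of stromal cells and marrow macrophages, was 6.15-fold lower (-2.62 ± 0.17, adjusted p = 0.0242), and Ltf, the gene of the neutrophil granule protein lactoferrin, was 6.83-fold lower (-2.77 ± 0.23, adjusted p = 0.0398).

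**Figure D1:**
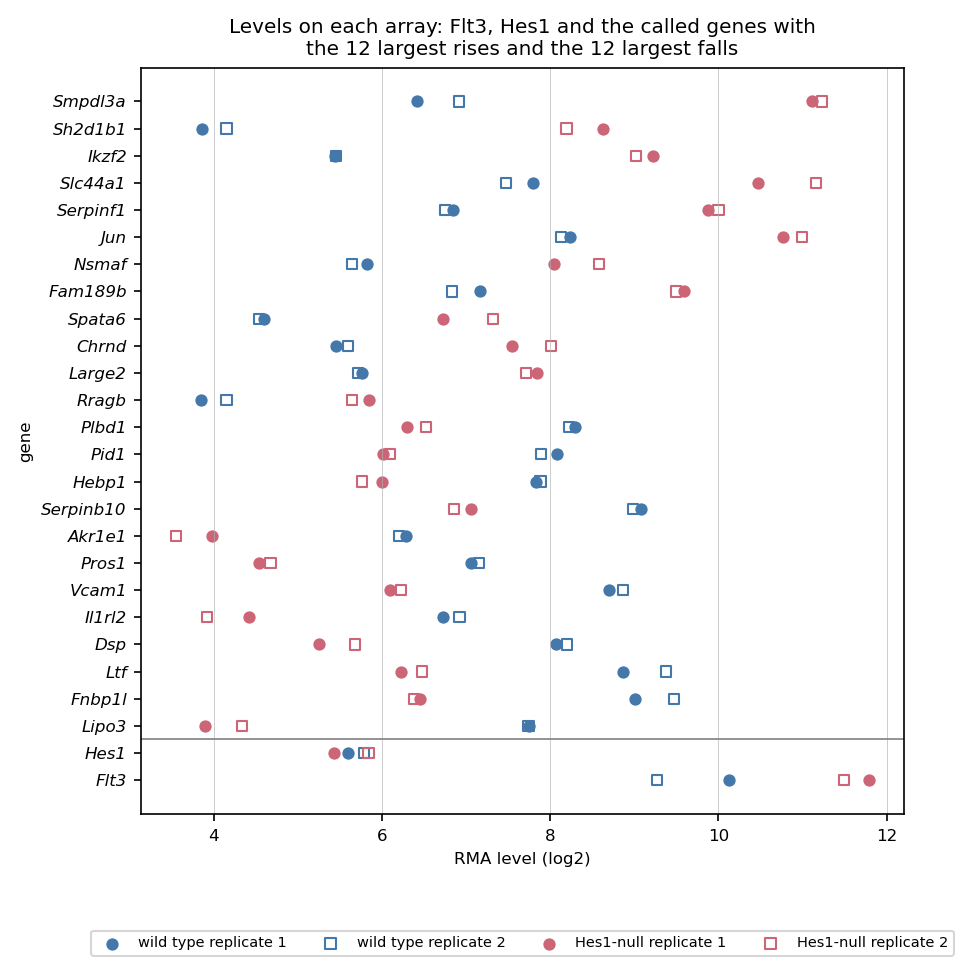
Each row is a gene and each mark 1 array, with the RMA level (log2) on the horizontal axis, blue for wild type, red for Hes1-null, filled circles for replicate 1 and open squares for replicate 2. In the called genes with the 12 largest rises and the 12 largest falls both marks of one genotype lie above both marks of the other, while those of Hes1 overlap and those of Flt3 lie at 9.27 and 10.13 in wild type against 11.50 and 11.79 in Hes1-null.

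Other genes that rose were Slc44a1 (3.18 ± 0.28), a choline transporter gene, and Serpinf1 (3.14 ± 0.17), which encodes a secreted serpin that restrains vessel growth. Nsmaf (2.59 ± 0.22), whose product links a tumor necrosis factor receptor to neutral sphingomyelinase, rose as well. Smaller rises were measured for Fam189b (2.54 ± 0.19), Spata6 (2.46 ± 0.22), the acetylcholine receptor subunit gene Chrnd (2.25 ± 0.20) and the glycosyltransferase gene Large2 (2.04 ± 0.15). Rragb, a GTPase gene of amino acid sensing, rose at least 3.08-fold. The chemokine gene Ccl3 rose 2.56-fold (1.35 ± 0.11, adjusted p = 0.0387) from an already high level of 11.65 in wild type. Further genes that fell were Fnbp1l (-2.82 ± 0.21), the desmoplakin gene Dsp (-2.67 ± 0.20) and Il1rl2 (at least 5.95-fold), which encodes the interleukin-36 receptor. Pros1, the gene of the anticoagulant protein S, differed by -2.50 ± 0.14. Akr1e1 (at least 4.46-fold), Serpinb10 (-2.08 ± 0.17), the heme-binding protein gene Hebp1 (-1.97 ± 0.16), Pid1 (-1.93 ± 0.16) and the phospholipase B gene Plbd1 (-1.85 ± 0.17) also fell. Each of these genes had an adjusted p under 0.05 and arrays that did not overlap between genotypes. A fold is given as a bound for the 5 genes with an array of the lower genotype at or below 4.09, since such a level is not shown to lie above background.

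In all, 29 of 19938 genes passed an adjusted p of 0.05 in limma's moderated test, 14 higher and 15 lower in Hes1-null marrow, with absolute log2 differences from 1.35 to 4.50. At an unadjusted p of 0.05 there were 1652 genes, 699 higher and 953 lower. Without any test, 398 genes were at least 2-fold apart with non-overlapping genotypes, 155 higher and 243 lower in Hes1-null marrow. The 2 other ways to split the 4 arrays into pairs gave 39 and 32 such genes. By limma those splits gave 0 genes at the adjusted threshold and 440 and 382 at the unadjusted one. Each of those splits puts both genotypes in each group, so a genotype difference adds to the spread within groups. Their counts are therefore not a chance baseline. Genotypes did not overlap for 7578 genes (38.0%), where chance gives 33.3%. The 29 called genes were all among these, so no array's removal could change their sign. The number of calls depended on the arrays: it was 35 without wild-type replicate 1, 6 without wild-type replicate 2, 999 without Hes1-null replicate 1 and 15 without Hes1-null replicate 2, with 15, 5, 29 and 7 of the 29 genes still called and all 29 of the same sign. It also depended on the genes tested, with 5 calls among genes at or above the median level and 0 when all probe sets, including unnamed ones and those with several symbols, were each tested (2809 at an unadjusted p under 0.05 by limma), but 30 when each probe set with 1 symbol was tested, an alternative chosen after seeing the data.

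Immediate early genes stood higher on both Hes1-null arrays. The list of immediate early and heat shock genes, fixed as a sign of sample handling, rose as a group (19 measured, median 1.34, adjusted p = 4.16e-11 by camera; adjusted p = 0.443 with an estimated correlation). Jun passed the test over all genes. With p adjusted over the list alone, 10 members rose and 0 fell. They included Dusp1 (2.15 ± 0.24), a phosphatase gene of the MAP kinase pathway, Zfp36 (1.34 ± 0.18), which encodes an mRNA decay factor, and the AP-1 gene Jund (1.42 ± 0.23). The 6 measured heat shock members did not share the shift as a group, with a median of -0.09, but they were mixed. Of the 19 list members, 15 were higher on both Hes1-null arrays than on both wild-type arrays, and 2 were lower on both. The 13 immediate early members were all among the 15, and heat shock members made up the rest. The median of the whole list stayed between 1.04 and 1.54 when each array was left out in turn.

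NF-kB and inflammatory genes also rose as a group (26 measured, median 0.43, adjusted p = 1.50e-05 by camera; adjusted p = 0.616 with an estimated correlation). Adjusted over the list alone, 4 members were higher, among them the chemokine genes Ccl3, Cxcl2 (4.76 ± 0.73) and Ccl4 (2.66 ± 0.48), and 1 was lower, Tnfaip2 (-1.40 ± 0.17). The median was 0.07 without Hes1-null replicate 2 (adjusted p = 0.0354) and 0.81 without Hes1-null replicate 1. Feedback and target genes of ERK signalling rose as a group (22 measured, median 0.29, adjusted p = 0.000472; adjusted p = 0.629 with an estimated correlation). None of them was called over the list alone, and Egr1, Ier3, Etv5 and Fosl1 differed by 1.72 ± 0.38, 1.16 ± 0.35, 0.45 ± 0.17 and -0.47 ± 0.21. The call of this list ended without Hes1-null replicate 2 (median 0.10, adjusted p = 0.166), and without Hes1-null replicate 1 the median was 0.54. Ribosomal protein genes shifted by a small amount (20 measured, median 0.10, adjusted p = 0.00258; adjusted p = 0.443 with an estimated correlation), with 0 called over the list alone. That call ended when the arrays were quantile normalized again (median 0.064, adjusted p = 0.0679).

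Genes of the myeloid lineage were lower in Hes1-null marrow in 3 lists. Monocyte and macrophage genes fell as a group (30 measured, median -0.52, adjusted p = 6.79e-10 by camera; adjusted p = 0.443 with an estimated correlation). Vcam1 was called over all genes, and 10 members fell with p adjusted over the list alone. Among these were the fractalkine receptor gene Cx3cr1 (-2.43 ± 0.30), the transcription factor gene Irf8 (-0.84 ± 0.12) and F13a1 (-0.93 ± 0.15). The list of neutrophil primary granule genes, which also holds transcription factor genes, fell as a group (15 measured, median -0.49). Its adjusted p by camera was 1.38e-07, and 0.443 with an estimated correlation. Over the list alone 6 members fell and 0 rose, including the protease genes Elane (-1.61 ± 0.18) and Prtn3 (-0.80 ± 0.10), Fcnb (-3.41 ± 0.45) and Ms4a3 (-3.06 ± 0.50). Late neutrophil genes fell as a group (22 measured, median -0.76, adjusted p = 2.60e-06; adjusted p = 0.601 with an estimated correlation). Over the list alone 5 fell, among them Ltf, the antimicrobial peptide gene Camp (-2.63 ± 0.51), Cd177 (-1.69 ± 0.32) and Mmp25 (-0.59 ± 0.14). Without Hes1-null replicate 1 the late neutrophil call ended (median -0.58, adjusted p = 0.0522), and without wild-type replicate 2 the median was -0.49. Leaving out each array moved the median of the monocyte list between -0.62 and -0.49 and that of the primary granule list between -0.76, without Hes1-null replicate 1, and -0.35, without Hes1-null replicate 2.

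Markers of several other marrow cell types moved the same way as the myeloid genes. Megakaryocyte and platelet genes fell as a group (14 measured, median -0.37, adjusted p = 0.000400; adjusted p = 0.443 with an estimated correlation). Over the list alone 4 fell, the platelet chemokine gene Ppbp (-1.91 ± 0.23), the integrin genes Itgb3 (-0.91 ± 0.21) and Itga2b (-0.69 ± 0.19), and Vwf (-0.54 ± 0.14). Stromal and endothelial genes fell as a group (23 measured, median -0.19, adjusted p = 0.000137; adjusted p = 0.443 with an estimated correlation). Over the list alone 5 fell, including Lpl (-2.73 ± 0.35), the matrix protein gene Sparc (-0.99 ± 0.15) and the niche chemokine gene Cxcl12 (-0.87 ± 0.15). T cell genes fell as a group (19 measured, median -0.22, adjusted p = 0.0130; adjusted p = 0.443 with an estimated correlation), with 1 gene lower over the list alone, Cd28 (-2.37 ± 0.40). NK and cytotoxic genes fell as a group (16 measured, median -0.13, adjusted p = 0.0431; adjusted p = 0.474 with an estimated correlation), with 0 called over the list alone. The T cell and NK lists were dim, with median levels of 5.52 and 4.77 against 6.36 over all genes. Without Hes1-null replicate 1 the calls of all 4 lists ended, with medians of -0.31 (adjusted p = 0.0991) for platelet, -0.12 (0.0962) for stromal, -0.12 (0.116) for T cell and -0.077 (0.348) for NK genes. Without Hes1-null replicate 2 the stromal median was -0.31. The T cell call also ended without Hes1-null replicate 2, where the median was -0.20 (adjusted p = 0.0611). The NK call ended with a smaller median without wild-type replicate 1 (-0.088, 0.106), and with a median of the same size or larger without Hes1-null replicate 2 (-0.19, 0.0566), with array weights (-0.13, 0.0681) and at the 25th percentile filter on level (-0.26, 0.0867). The B cell list was not called (24 measured, median 0.0019, adjusted p = 0.795). The erythroid list was not called either (22 measured, median -0.14, adjusted p = 0.0512), and which array was left out decided its call. Its median was -0.26 (0.00267) without wild-type replicate 2 and -0.27 (0.0102) without Hes1-null replicate 2, but -0.071 (0.395) without wild-type replicate 1 and -0.036 (0.599) without Hes1-null replicate 1. It also passed after centring the arrays (0.0367) and with array weights (0.0495), and at the median filter its median was -0.57 (0.412).

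Cholesterol synthesis genes fell as a group (19 measured, median -0.30, adjusted p = 0.000284; adjusted p = 0.629 with an estimated correlation). Over the list alone 3 fell, the squalene epoxidase gene Sqle (-1.84 ± 0.35), Fdps (-1.31 ± 0.27) and Srebf2 (-0.65 ± 0.16), which encodes a regulator of the pathway. Genes of the G2 and M phases of the cell cycle fell as a group (28 measured, median -0.23, adjusted p = 0.000776; adjusted p = 0.698 with an estimated correlation). Of these, 27 had a negative difference and 0 were called over the list alone, with Kif23 at -0.47 ± 0.18 and Mki67 at -0.33 ± 0.13. Both calls ended without Hes1-null replicate 2, with medians of -0.13 (adjusted p = 0.243) for cholesterol synthesis and -0.019 (adjusted p = 0.935) for the G2 and M phases, against -0.46 and -0.45 without Hes1-null replicate 1. Adhesion and homing genes fell as a group (20 measured, median -0.16, adjusted p = 0.00258; adjusted p = 0.474 with an estimated correlation). Besides Vcam1, the tetraspanin gene Cd9 (-1.32 ± 0.20) and Cd93 (-0.58 ± 0.12) fell over the list alone. The median was -0.26 without wild-type replicate 1, -0.24 without Hes1-null replicate 2 and -0.086 without wild-type replicate 2.

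**Figure D2:**
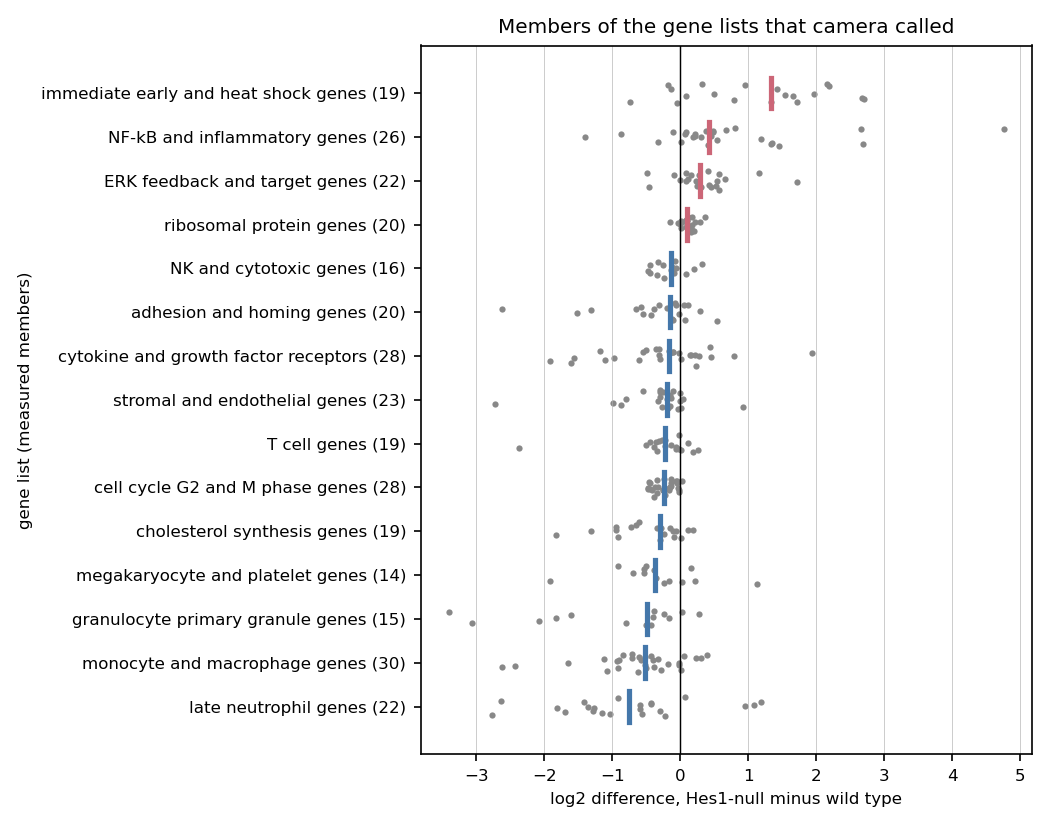
Each point is a measured member of 1 of the 15 gene lists that camera called, with its log2 difference (Hes1-null minus wild type) on the horizontal axis, and each bar is the list's median, red for lists that were higher and blue for lists that were lower. Medians run from 1.34 for immediate early and heat shock genes to -0.76 for late neutrophil genes, and single members of each list lie on both sides of 0.

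Flt3, which encodes a receptor tyrosine kinase of hematopoietic progenitors, lay at 10.13 and 9.27 on the wild-type arrays and at 11.79 and 11.50 on the Hes1-null arrays. The difference was 1.94 ± 0.30 (3.84-fold, 95% interval 1.19 to 2.70), with an unadjusted p of 0.000986 and an adjusted p of 0.142 by limma, so it did not pass the threshold over all genes. Flt3 is known as a candidate that the study chose, and its value here is not independent evidence. With the replicate number as a block, Flt3 had an adjusted p of 0.0246 by limma, but the labels do not say what a number shares. With 1 array left out its adjusted p ranged from 0.0316, without wild-type replicate 1 (difference 2.37), to 0.183, and with array weights it was 0.218. Cytokine and growth factor receptors fell as a group (28 measured, median -0.16, adjusted p = 0.0364; adjusted p = 0.491 with an estimated correlation). Over the list alone 1 member was higher, Flt3, and 7 were lower, including the chemokine receptor gene Ccr2 (-1.91 ± 0.20), Igf1r (-0.98 ± 0.21) and Axl (-0.61 ± 0.13). The list was not called without wild-type replicate 2 (median -0.14, adjusted p = 0.0522) or Hes1-null replicate 1 (-0.13, 0.297), nor with filters on level at the 25th percentile (-0.13, 0.130) or the median (-0.062, 0.401).

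Genes of the Notch pathway showed no shift as a list (39 measured, adjusted p = 0.348), with a median of -0.01, a mean of 0.07 and an upward direction by camera. Of its members, 0 passed the test over all genes and 1, the Hes family gene Hes6 (1.22 ± 0.18), was higher over the list alone. Dtx3, Tle3 and Maml1 had differences of 0.62 ± 0.20, 0.69 ± 0.22 and 0.75 ± 0.26, which did not pass either. Targets of MLL fusion proteins were not shifted (28 measured, median 0.14, adjusted p = 0.221), although over the list alone Tcf4 (1.82 ± 0.18) was higher and Runx1 (-0.92 ± 0.15) lower. Without Hes1-null replicate 2 that list was called (median 0.12, adjusted p = 0.0451), and without Hes1-null replicate 1 its median was 0.013 (adjusted p = 0.703). Stem and progenitor genes were not shifted (24 measured, median -0.03, adjusted p = 0.184) and held 0 called members, with Angpt1 at -1.15 ± 0.21. Myeloid transcription factors were not shifted either (24 measured, median -0.0013, mean 0.11, adjusted p = 0.808), upward by mean and by camera. Over that list alone 3 were higher and 2 lower, among them Jun, Egr1, Runx1 and Irf8. Genes of S phase missed the threshold (24 measured, median -0.11, adjusted p = 0.0512), and which array was left out decided their call. They passed without wild-type replicate 2 (median -0.22, 0.0229) and without Hes1-null replicate 1 (median -0.33, 9.72e-05), but not without wild-type replicate 1 (median -0.054, 0.337) or Hes1-null replicate 2 (median -0.0019, 0.753). They also passed after a further quantile normalization (0.0413), without the intensity trend (0.0479) and with array weights (0.0306).

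Camera called 15 of the 33 lists tested, 4 higher and 11 lower. With an estimated correlation between genes it called 0, with a smallest adjusted p of 0.443 and 1 list at an unadjusted p under 0.05. The fry test asks whether a list's genes move on balance in 1 direction, without comparing them with other genes. It called 0 lists, with a smallest adjusted p of 0.172 and 8 lists at an unadjusted p under 0.05. No shift was called for dendritic cell and antigen presentation genes (median 0.07, adjusted p = 0.308), where Tcf4 was higher over the list alone. Apoptosis regulators (median 0.00029, adjusted p = 0.829), interferon stimulated genes (median -0.03, adjusted p = 0.621) and housekeeping genes (median 0.0033, adjusted p = 0.348) were not called. Respiratory chain genes (median 0.04, adjusted p = 0.234) and glycolysis and hypoxia genes (median -0.04, adjusted p = 0.961) were not called, and Ndrg1 (-1.46 ± 0.25) of the latter fell over the list alone. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333.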

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

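Probe sets that the platform annotation does not list entered no comparison of genes, and their count was chosen after the data were examined. Of these 12146 probe sets, 282 had a Hes1-null mean at least 2-fold above the wild-type mean, with no overlap of arrays between genotypes. By the same rule 116 were lower, which makes 398 in all. The same count over the other splits of the 4 arrays was 255 and 150, which is no chance baseline, since those splits mix the genotypes. Among named genes the balance lay the other way, with 155 higher and 243 lower. The unnamed probe sets varied more between arrays of a genotype, with a median residual SD of 0.22 (log2) against 0.16 for probe sets with 1 gene symbol. No explanation was tested for the excess of higher probe sets.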

How the results depend on the processing

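All 29 called genes kept their sign wherever they were tested. Leaving out 1 array could not change it, since their arrays did not overlap between genotypes. Settings that change only the estimated spread could not change it either. The number of calls (14 higher and 15 lower) was less stable, and the cause was not tested. The submitters speak of pairs of both genotypes but not of what a pair or a replicate number shares, so the numbers were not read as pairs. Arrays with the same number did not deviate together (r = 0.0505 across genes), which does not exclude a pair effect at single genes. With the replicate block there were 44 higher and 45 lower, Flt3 passed the threshold (1.94, adjusted p = 0.0246), and so did the lists of S phase (0.0291), erythroid (0.0464) and STAT target genes (0.0285). Array weights gave 22 and 23, a further quantile normalization 21 and 25, and robust moderation 9 and 14. With fewer genes tested, the 25th percentile filter gave 7 and 10 and the median filter 4 and 1. Of the 29 called genes, 26 were still tested at the 25th percentile filter and 17 were called. At the median filter 18 were still tested and 5 were called. All probe sets, each tested on its own with the unnamed and multi-symbol ones added, gave 0 and 0 (smallest adjusted p 0.0790 by limma), while those with 1 symbol, an alternative chosen after seeing the data, gave 15 and 15. The count was also 0 and 0 with an ordinary two-sample test without moderation (1438 genes with an unadjusted p under 0.05, smallest adjusted p 0.228). An adjusted p under 0.10 gave 41 and 50, and an unadjusted p under 0.05 with a 2-fold difference gave 140 and 226. Leaving out 1 array gave 3 to 314 higher and 3 to 685 lower, the highest without Hes1-null replicate 1. The count of genes 2-fold apart stayed between 321 and 409 in the other settings, ran from 418 to 782 with 1 array left out, and was 1129 at 1.5-fold. Flt3's difference ran from 1.51 to 2.37 and that of Hes1 from -0.26 to 0.15 with 1 array left out; Hes1 lay under the median level, so that filter gave no value for it. Lists called numbered 12 to 18 in all settings except camera with an estimated correlation (0) and fry (0).

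Some values near 0 changed sign. Over the leave-one-out fits Srm ran from -0.97 to 0.24 and Tubb5 from -0.23 to 0.030. In the same fits list medians ran from -0.043 to 0.057 for Notch, -0.13 to 0.38 for STAT targets, -0.066 to 0.12 for dendritic cell genes, -0.047 to 0.023 for B cell genes and -0.0077 to 0.14 for p53 targets. They ran from -0.067 to 0.17 for apoptosis regulators, -0.51 to 0.28 for MYC targets, -0.049 to 0.079 for glycolysis, -0.015 to 0.13 for the respiratory chain, -0.064 to 0.048 for housekeeping genes and -0.065 to 0.16 for myeloid transcription factors. At the 25th percentile filter the median was 0.0053 for stem and progenitor genes, -0.025 for B cell genes, 0.0028 for interferon stimulated genes and 0.060 for myeloid transcription factors. At the median filter it was 0.037 for Notch, 0.027 for stem and progenitor genes, 0.022 for interferon stimulated genes and 0.060 for myeloid transcription factors. It was -0.018 for housekeeping genes after a further quantile normalization, 0.0046 for myeloid transcription factors after centring and -0.013 for apoptosis regulators with the mean of a gene's probe sets. None of these lists was called in the main test, and the cause was not tested.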

Other observations

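The tests of Y-linked genes, of the primary granule genes and of the other cell types were chosen only after the results they concern had been seen. In the tests of explanations below, an SE in brackets is over the genes of a set, taken as independent. Unlike the ± values, it does not measure the spread between arrays. List members can move together, with estimated correlations of 0.47 for the ERK list and 0.49 for late neutrophil genes. MYC targets and genes of ribosome biogenesis had a median difference of -0.08 over 25 members and were not called (adjusted p = 0.961), yet the Hes1-null arrays lay on opposite sides of wild type. With Hes1-null replicate 2 left out the median was 0.28, and with Hes1-null replicate 1 left out it was -0.51. The correlation estimated for this list was 0.81, far above the preset 0.01. The polyamine synthesis gene Srm, one of the members, had a difference of -0.37 ± 0.38 with both arrays. Respiratory chain genes had a median of 0.13 without Hes1-null replicate 2 and of -0.015 without Hes1-null replicate 1.

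The eosinophil granule protein genes Prg2 and Epx differed by -1.67 ± 0.45 and -1.15 ± 0.37, and Siglecf, a surface receptor gene of eosinophils, by -1.61 ± 0.39, none of which passed over all genes or over the list alone. Their list of mast cell, basophil and eosinophil genes was not called either (17 measured, 6 of them positive, median -0.17, adjusted p = 0.106). It was called without wild-type replicate 1 (median -0.30, adjusted p = 0.000185) and at the 25th percentile filter (median -0.82, adjusted p = 0.0300), and its median was -0.057 (adjusted p = 0.486) without Hes1-null replicate 1. Among STAT targets (14 measured, median 0.17, adjusted p = 0.106), the cytokine gene Osm was 6.87-fold higher (2.78 ± 0.40) and passed over the list alone. That list was called without Hes1-null replicate 1 (median 0.38, adjusted p = 0.0119), without wild-type replicate 2 (median 0.25, adjusted p = 0.0183) and at the 25th percentile filter (median 0.33, adjusted p = 0.0475), but its median turned to -0.13 (adjusted p = 0.825) without Hes1-null replicate 2 and was 0.11 (adjusted p = 0.120) without wild-type replicate 1. Among p53 targets and cell cycle inhibitors (22 measured, median 0.08, adjusted p = 0.176), Pmaip1 (1.32 ± 0.24) and Btg2 (1.07 ± 0.20) passed over the list alone, and without wild-type replicate 2 that list was called (median 0.14, adjusted p = 0.0282). Its median turned to -0.0025 (adjusted p = 0.334) without wild-type replicate 1 and to -0.0077 (adjusted p = 0.458) without Hes1-null replicate 2. Plasma cell genes were not called (8 measured, median -0.20, adjusted p = 0.112), with Irf4 (-0.62 ± 0.12) and Prdm1 (-0.50 ± 0.12) lower over the list alone and Sdc1 at 0.73 ± 0.28. The median was -0.33 (adjusted p = 0.132) without Hes1-null replicate 1 and -0.079 (adjusted p = 0.935) without Hes1-null replicate 2.

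Xist was 22.3-fold lower on Hes1-null replicate 2 than on Hes1-null replicate 1. RNA from a male is argued against by the Y-linked genes, whose median differed by 0.12 (SE 0.10, log2) between these arrays. A silenced Xist with both X chromosomes active is argued against by 265 X-linked genes, which lay at -0.12 (SE 0.04) relative to 9679 autosomal genes. The 6 listed genes that escape X inactivation were all lowest on replicate 2, with a median of -0.52 (SE 0.10) against replicate 1, in line with a loss of the inactive X chromosome; 273 of 10000 random autosomal sets were as low. This stays a hypothesis on 1 array, and no biological explanation from the genotypes was tested.

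All 13 immediate early genes of the list were higher on both Hes1-null arrays than on both wild-type arrays, with a median difference of 1.66 (3.16-fold) and a range from 0.49 to 2.70. A stress response that raises heat shock genes as a group is argued against by the 6 heat shock members, whose median was -0.0946 (SE 0.18). These members were mixed, and single ones did rise. Of the 19 list members, 15 were higher on both Hes1-null arrays, the 13 immediate early genes among them, and 2 were lower on both. A single array is argued against as well, since the list's lowest median with 1 array left out was 1.04. ERK signalling above that of wild type stays open: 11 feedback genes outside the list had a median of 0.45 (SE 0.07), but 0.11 on Hes1-null replicate 1 and 0.72 on replicate 2. The genotype and differences in sample handling, which the labels do not record, may each contribute and were not tested.

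Most neutrophil and monocyte genes of the lists were lower on the Hes1-null arrays. Differences were negative for 18 of 22 late neutrophil, 25 of 30 monocyte and 13 of 15 primary granule genes. With an estimated correlation camera called 0 of these lists. A smaller share of mature neutrophils alone predicts no fall of primary granule genes, which promyelocytes make. The mean difference of their list was -1.01 (SE 0.29) and the median -0.49. That list is not limited to granule genes and holds, among others, the transcription factor genes Cebpe and Gfi1. Its fall therefore cannot decide the matter. For the late neutrophil genes a smaller share of mature neutrophils stays open too. The SD of their differences was 1.06 (SE 0.17), too close to 1 to decide. A smaller share of every non-leukemic cell type also stays open: the highest of 5 lineage medians was 0.0019 (SE 0.07), for B cell genes. B cell genes were dim, with a median level of 5.58 against 6.36 over all genes. T cell genes, at 5.52, and NK genes, at 4.77, were dimmer still, so dim levels limit these lists as well. The median difference of platelet genes was -0.37. A direct effect of the genotype on leukemic cells was not tested and may hold beside these explanations.

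Flanking DNA carried along with a mutation is a hypothesis for genes next to Hes1. Of its 40 nearest measured neighbours 1 had an unadjusted p under 0.05 by limma, namely Bdh1 (1.05 ± 0.17), against 8.33% of autosomal genes. This gives no sign of an effect on many neighbours. A count cannot exclude an effect on single neighbours, and Bdh1 itself was at least 2-fold apart with non-overlapping genotypes. A gain or loss of a whole chromosome was read from chromosome medians against the other arrays. The most extreme was -0.18, for the X chromosome on Hes1-null replicate 2, where the median over chromosomes was -0.08, and it could not decide either way.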
